A study of Mus musculus with 12 samples.

How the data were processed

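RNA was measured in muscle from male db/db mice, which lack a working leptin receptor and become obese and diabetic. The mice were on the C57BL/KsJ background and were 8 weeks old when they were randomly assigned to 4 groups of 3, per the labels' protocols. The groups were normal rearing (control), high-intensity interval training (HIIT), semaglutide injection (a long-acting agonist of the GLP-1 receptor) and both interventions together (combination). HIIT was run on a treadmill in 10 bouts of 4 min at 85 to 90% of maximal speed with 2 min of recovery, 5 days a week for 8 weeks. Semaglutide was given subcutaneously, at 30 nmol/kg daily in the protocol text and at 0.05 mg/kg in the sample titles, 2 statements of the dose that were not reconciled here. The labels call the samples muscle. The protocol names soleus among the harvested tissues, beside heart, kidney, hippocampus and liver.

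Total RNA was extracted with TRIzol, and poly(A) RNA was made into stranded libraries and sequenced paired-end on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes list CASAVA, FastQC, Trimmomatic 0.36, STAR 2.7.9a, featureCounts 2.0.1, StringTie 2.1.4 and the mouse build GRCm39, without a role for each. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the depth of the library) for the 12 libraries. Which tool gave the FPKM, the annotation release and any filter on genes are not given in the sources used here. The table holds 22390 features with 1 value per library, of which 22105 carry Ensembl gene identifiers, 274 carry the MSTRG names that StringTie gives to assembled features and 11 carry transcript identifiers. In 4877 of them every library is at 0. Raw counts were not used here, so no count model was fitted.

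Depth is not stated for any library. It was estimated from the low end of the table, where the smallest FPKM steps of 4431 genes with a single annotated transcript give the worth of 1 fragment at a given length. The steps (53 to 70 values per library) correspond to 17.2 to 21.3 M fragments per library. At that depth an FPKM of 1 in a transcript of 1 kb stands for about 17 to 21 fragments, so values under 1 rest on few fragments. Transcript lengths and gene names for this step came from GENCODE M21, which belongs to GRCm38 and not to the authors' build, so no coordinates are given.

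The deposited FPKM were used without rescaling as log2(FPKM + 1), and a fold change is therefore on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. Genes with FPKM of at least 1 in at least 3 of the 12 libraries were kept, leaving 10666 genes, 90 of them MSTRG features. One linear model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (trended, robust empirical Bayes), so that all 12 libraries share 1 estimate of the spread. limma's moderated statistic gave 6 pairwise comparisons, the interaction of HIIT and semaglutide, each intervention averaged over the other, and an F test over the 4 groups. Tests were two-sided with Benjamini-Hochberg adjustment over all genes kept, and calls were made at an adjusted p of 0.05. Errors of fold changes are limma standard errors (SE) with 3 libraries per group. The replicates are numbered within groups and the labels do not describe each library's animal, so p-values measure the spread between these samples. Whether equal numbers pair the libraries was checked by the correlation of their deviations from the group means. Over 18 pairs it was -0.23 to 0.29, and 2 of 12 libraries matched best with their own number, so the numbers do not pair all 4 groups. The 3 pairs of HIIT with the combination were at 0.29, 0.27 and 0.22, and no label pairs them. That comparison is also given with a block within these 2 groups, picked because of these correlations. Such a block takes up the spread it was picked for, so its calls add no support.

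Lists of genes were compared with all other genes by camera from limma with a preset correlation of 0.01, with adjustment over the lists of a comparison. The same test with a correlation estimated from the residuals was run beside it. There were 33 lists of muscle pathways and 14 lists of markers of other cell types or organs, of which 45 had at least 5 tested members. The lymphocyte and neutrophil markers had 1 and 2 tested members and were not tested as lists. Genes were named by a fixed rule. The rule takes the 10 higher and 10 lower called genes with the largest fold change whose 3 libraries in one group lie apart from the 3 of the other (5 in each direction for averaged effects), or the 5 with the smallest p where fewer than 5 pass. It adds up to 4 members of each list past its threshold, 24 fixed genes of muscle metabolism and fibre type, and the 3 most abundant members of each marker list. Ribosomal proteins, globins, histone H1f2, Actg1 and the Serpina1, Mup and Saa families have close paralogs or pseudogenes, and their values are uncertain because shared reads could be split among copies.

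The groups, tests, filter, lists, rule for named genes and the first set of changed settings were fixed before the data were examined. That set held a pseudocount of 0.1, no filter, a filter at FPKM 5, rescaling by TMM factors computed on the FPKM (trimming 30% of ratios and 5% of levels), limma array weights, fits on the 6 libraries of a comparison only, the replicate number as a block, an estimated correlation for camera, and leaving out each library in turn. Another 4 were added after liver and fat transcripts and library medians had been seen. These were fits without the 3 libraries with the most liver transcripts, with a liver score or an adipocyte score as a covariate, and without combination replicates 2 and 3.

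The scripts were tested on simulated data before use. With 200 of 10666 genes changed in 20 simulated semaglutide sets, 41.4% of changes of 0.5 on the log2 scale, 83.6% of changes of 1, 93% of changes of 1.5 and 96.5% of changes of 2 were recovered. Of the calls 5.3% were false, and the unchanged comparison gave 1 call. A simulated list of 30 genes shifted by 0.4 was called by camera in 20 of 20 sets, and an unshifted one in 1. The changed genes were drawn from those with a mean log2(FPKM + 1) above 1, and noise was drawn independently for each gene. Recovery of weaker genes was therefore not tested, nor was camera's preset correlation where genes vary together. Results for some of the genes that the rule names are not reported here. Figures and summaries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.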

Results

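Transcript levels were measured in 12 muscle libraries from db/db mice, 3 each from control, HIIT, semaglutide and combination groups. The deposited FPKM summed to between 533412 and 586817 per library, 14559 to 15875 features lay above 0, and 9181 to 10690 reached an FPKM of 1. The estimated depth was 17.2 to 21.3 M fragments. Mitochondrially encoded transcripts made up 31.3 to 42% of the FPKM, and the 10 most abundant genes 33.4 to 40%. The fast myosin Myh4 accounted for 82.3 to 95% of the FPKM of the 4 adult myosin heavy chains, and the slow myosin Myh7 for 0.0559 to 1.52%. Across genes, replicates correlated at r of 0.971 to 0.981 in controls, 0.97 to 0.979 under HIIT, 0.988 to 0.989 under semaglutide and 0.977 to 0.991 in the combination group.

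**Figure D1:**
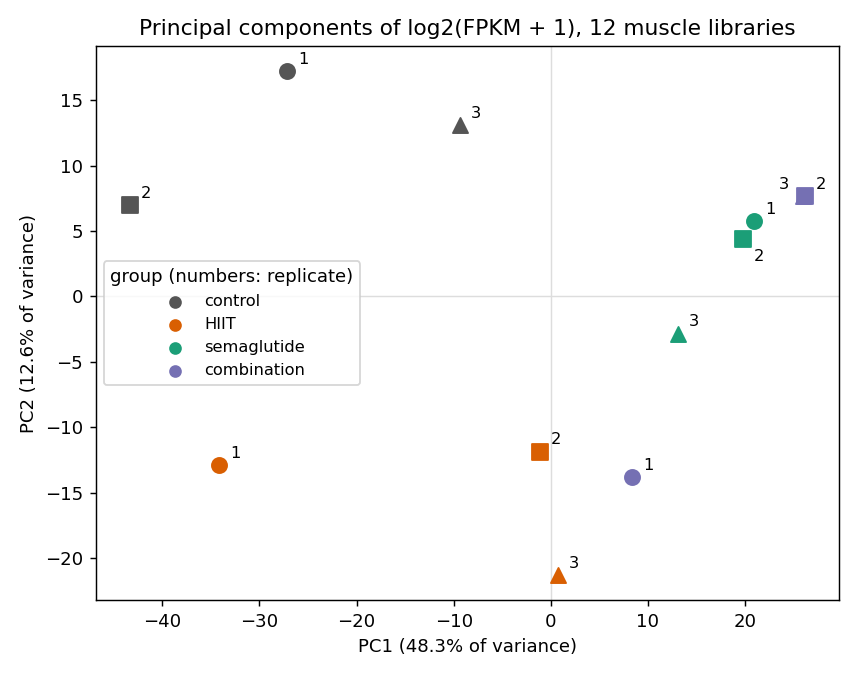
Each point is 1 library placed on the first and second principal components of log2(FPKM + 1) over the tested genes (48.3 and 12.6% of the variance), coloured by group and numbered by replicate. The 6 libraries of injected mice lie at PC1 of 8.399 to 26.16 and the controls at -43.38 to -9.313, while combination replicate 1 lies apart from replicates 2 and 3 of its group.

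Markers of tissues other than skeletal muscle differed between libraries. Alb, which encodes serum albumin and is made by hepatocytes, stood at 399, 714 and 108 FPKM in the 3 controls, at 178, 27.6 and 3.8 under HIIT, and at 0.77 to 3.57 in the 6 libraries of injected mice. All of 18 liver genes examined were higher in every control than in every library of an injected mouse. The adipocyte hormone gene Adipoq was at 6.78, 44.8 and 14.4 FPKM in controls and at 77.6, 51.2 and 39.9 under HIIT. It was at 9.6, 8.54 and 30.5 under semaglutide, and 52.8, 15.8 and 10.7 in the combination group. The macrophage gene Cd68 lay at 13.1, 4.66 and 15.2 FPKM under HIIT and at 2, 9.37 and 1.3 in controls. Myh7 was at 48.2 to 108 FPKM in controls and at 5.27 to 73.1 in the 9 other libraries. Combination replicates 2 and 3 had the lowest TMM factors, both 0.866, and medians of log2(FPKM + 1) of 2.51 and 2.5, against 1.01 and 2.7 for combination replicate 1.

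**Figure D2:**
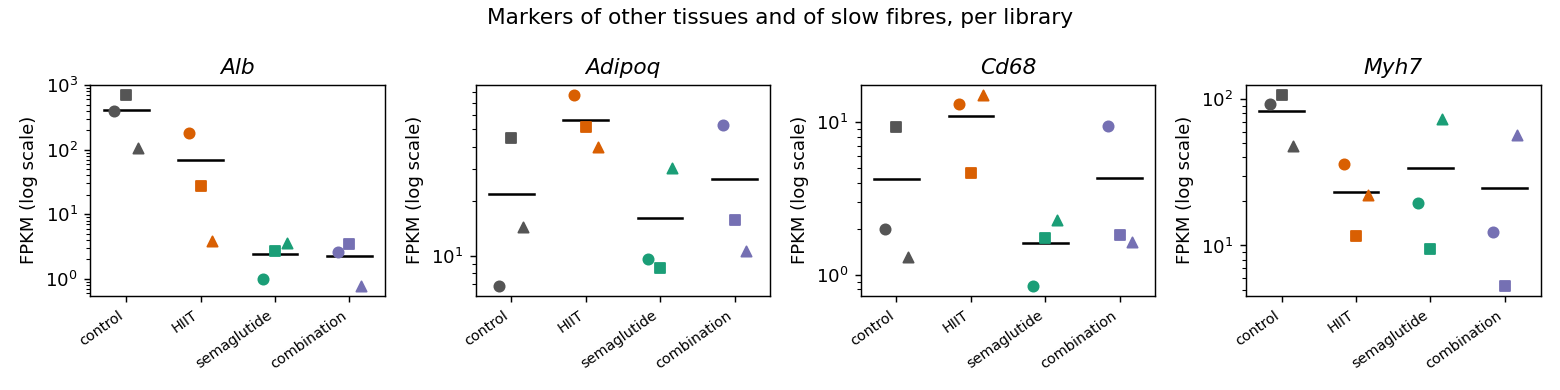
FPKM of a liver gene (Alb), a fat gene (Adipoq), a macrophage gene (Cd68) and slow myosin (Myh7) per library on log axes, with circle, square and triangle for replicates 1, 2 and 3 and a line at each group mean. Alb falls from 108 to 714 in controls to 0.77 to 3.57 in injected mice, and Adipoq is at 39.9 to 77.6 in all 3 HIIT libraries.

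The first comparison asked what 8 weeks of HIIT changed against normal rearing. No single gene passed the threshold. The nearest among named genes was Bltp1, a lipid transfer protein gene, at -0.88 ± 0.13 (SE, n = 3 per group, adjusted p = 0.235). The collagen chaperone Serpinh1 was at 1.03 ± 0.22, the matrix protein dermatopontin (Dpt) at 0.95 ± 0.17, the histone variant H2az1 at 0.45 ± 0.08 and acetylcholinesterase (Ache) at -0.73 ± 0.16. The last 4 had an adjusted p of 0.437. Ppargc1a, a regulator of mitochondrial biogenesis, was at 0.38 ± 0.15 (adjusted p = 0.467). limma called 0 genes at adjusted p of 0.05, with 952 at an unadjusted p under 0.05 (351 higher, 601 lower) where 533 would arise by chance. Leaving out control replicate 3, HIIT replicate 1 or HIIT replicate 2 gave 1 call.

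Gene lists moved together under HIIT without any member passing over all genes. Of 45 lists, 13 passed camera with the preset correlation and 0 with an estimated one, where every list had an adjusted p = 0.906 with an estimated correlation. Nuclear genes of respiratory complexes II to V (median 0.21 over 39 members, adjusted p = 5.36e-11) and of complex I (0.16 over 36, 1.57e-08) stood higher, for example Uqcr11 at 0.31 ± 0.10 and Cox8b at 0.32 ± 0.11. Extracellular matrix genes (0.44 over 31, 6.71e-11) and fibroblast markers (0.37 over 15, 5.58e-06) stood higher too, and 4 members of each rose when adjusted over the list alone, against 0 over all genes. Col1a1, a chain of type I collagen, was at 1.33 ± 0.35. All 14 white adipocyte markers (median 0.55, adjusted p = 0.000587) and all 12 macrophage markers (0.53, 0.00195) were above 0, with Adipoq at 1.65 ± 0.73. Ribosomal protein genes were at 0.10 over 52 members (0.000179) and mitochondrially encoded genes at 0.09 over 13 (0.0101). Lower lists were PPAR targets (-0.42 over 24, 0.000341), the slow fibre program (-0.79 over 17, 0.00125) and angiogenesis (-0.18 over 19, 0.0299). So were neuromuscular junction genes (-0.24 over 14, 0.0421, 3 members lower when adjusted over the list alone) and markers of other organs (-2.60 over 7, 0.000153, 4 lower when adjusted over the list alone). The latter's leading members are the liver genes Alb, Apoa1, Ttr and Serpina1a.

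Several of these list calls rested on single libraries. The macrophage call was lost without HIIT replicate 1 or 3 (adjusted p up to 0.245), the PPAR call (0.485) and the slow fibre call (0.0639) without HIIT replicate 2, and the ribosomal call without HIIT replicate 3 (0.0944). The mitochondrially encoded call was lost without control replicate 2, control replicate 3 or HIIT replicate 3 (up to 0.74). The neuromuscular call ended without control replicate 3, HIIT replicates 1 or 3 or semaglutide replicate 1 (up to 0.204), and that of angiogenesis without control replicates 1 or 3 or HIIT replicates 2 or 3 (up to 0.168). Other calls were kept while their medians moved. Without HIIT replicate 3 they were 0.09 for complex I, 0.10 for complexes II to V and -1.66 for markers of other organs. The matrix median was 0.27 without control replicate 3 or HIIT replicate 1, and the white adipocyte median 0.27 and 0.94 without control replicates 1 and 2. The fibroblast median was 0.59, 0.575 and 0.23 without control replicates 1, 2 and 3 and 0.78 without HIIT replicate 2. With an adipocyte score as a covariate, added after the data were seen, the medians of white adipocyte and macrophage markers were -0.04 and 0.07. Those of the complex II to V and matrix lists were 0.27 and 0.24, still past camera with the preset correlation.

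The next comparison asked what semaglutide injection alone changed. The treatment labels name no injection for control or HIIT mice, so the drug and the injecting cannot be told apart. The muscle ubiquitin ligase genes Fbxo32 and Trim63 and the glucocorticoid-induced Fkbp5 rose, and the plasma protein genes Alb, Apoa2 and Ttr fell. Fbxo32, which encodes the ubiquitin ligase atrogin-1, rose from 50.7 to 136 FPKM, a log2 change of 1.38 ± 0.20 (SE, n = 3 per group, adjusted p = 0.0113), and its partner Trim63 (MuRF1) rose from 210 to 433 FPKM, by 1.04 ± 0.22 (0.0319). The cell cycle inhibitor Cdkn1a rose by 1.69 ± 0.25, the glucocorticoid-induced chaperone Fkbp5 by 1.504 ± 0.20 and the metallothionein Mt2 by 1.92 ± 0.34. The kinase gene Sgk1 rose by 1.03 ± 0.14 and Jun, a transcription factor, by 1.44 ± 0.14 (adjusted p = 0.00151). The translation repressor Eif4ebp1 rose by 0.94 ± 0.11 and the autophagy kinase Ulk1 by 0.69 ± 0.10. Pik3r1, the regulatory subunit of PI3-kinase, rose by 1.54 ± 0.25 and Tbc1d1, which controls glucose transporter traffic, by 1.48 ± 0.20. They were the 2 of 28 insulin signalling genes that rose, and that list did not pass (median -0.01, camera 0.497; adjusted p = 0.859 with an estimated correlation). Alb fell by 6.61 ± 1.12, Apoa2 by 5.35 ± 1.09 and Ttr by 4.90 ± 0.93, from means of 407, 99.5 and 48.3 FPKM in controls.

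**Figure D3:**
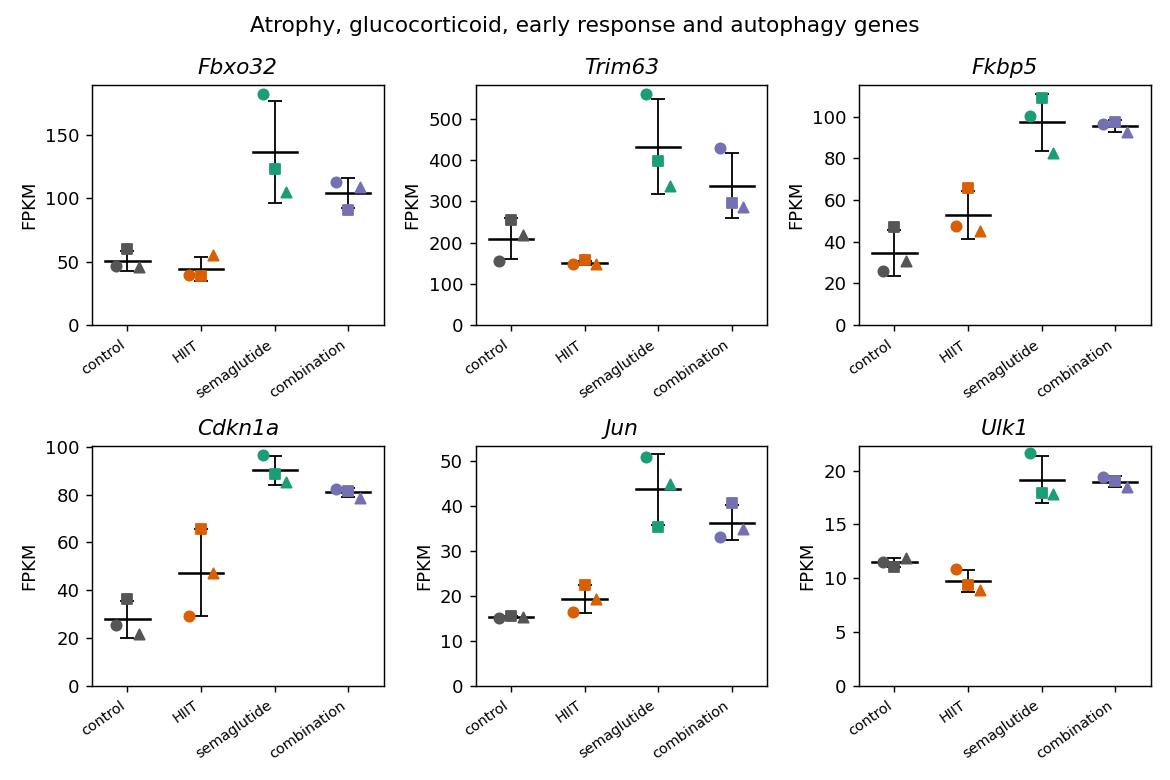
FPKM per library of 2 muscle ubiquitin ligases (Fbxo32, Trim63), a glucocorticoid target (Fkbp5), a cell cycle inhibitor (Cdkn1a), an early response gene (Jun) and an autophagy kinase (Ulk1), with the group mean as a line and the SD over 3 libraries as bars; circle, square and triangle are replicates 1, 2 and 3. Mean Fbxo32 is 50.7 in controls, 44.4 under HIIT, 136 under semaglutide and 104 in the combination group.

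By list, atrophy and FoxO targets had 9 of 22 members risen and 0 fallen (11 risen when adjusted over the list alone), with a median of 0.39 and a camera adjusted p of 2.07e-08, or adjusted p = 0.359 with an estimated correlation. Glucocorticoid response genes had 8 risen, 1 fallen and 12 that did not pass of 21 (11 and 2 adjusted over the list alone; median 0.69, 8.46e-07), and proteasome genes 1 risen of 31, Psmc2 at 0.42 ± 0.10 (3 adjusted over the list alone; median 0.20, 2.47e-10); for both, adjusted p = 0.704 with an estimated correlation. Immediate early genes had 2 of 24 risen, Jun and Ccn1 at 1.19 ± 0.26 (4 adjusted over the list alone; median 0.30, 0.00223; adjusted p = 0.704 with an estimated correlation). Their median was 0.19 without control replicate 3 and 0.17 and 0.115 without semaglutide replicates 1 and 3. Autophagy genes had 1 of 22 risen, Ulk1 (3 adjusted over the list alone; median 0.02, 0.047; adjusted p = 0.704 with an estimated correlation). Fbxo32 and Cdkn1a stand in both the FoxO and the glucocorticoid list.

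Matrix genes stood lower, with 1 of 31 fallen, the collagen VI gene Col6a3 at -0.83 ± 0.17 (6 adjusted over the list alone; median -0.53, camera 1.89e-05), and fibroblast markers had 0 of 15 fallen (3 adjusted over the list alone; median -0.44, 0.00325). All 12 macrophage markers were below 0 beside them (median -0.60, 0.158; adjusted p = 0.876 with an estimated correlation), with Cd74 at -1.24 ± 0.53 (adjusted p = 0.234) and Lyz2 at -0.97 ± 0.78 (0.544). Angiogenesis genes had 2 of 19 fallen (4 adjusted over the list alone; median -0.21, 0.00692), the VEGF receptor Kdr at -0.80 ± 0.19 and Angpt1 at -0.85 ± 0.19, and endothelial markers 1 of 15, also Kdr (4 adjusted over the list alone; -0.38, 0.0198). PPAR targets had 4 of 24 fallen (6 adjusted over the list alone; -0.44, 0.00402), among them Cyp4a10, Cyp4a14 and Creb3l3, genes that the liver expresses strongly. The slow fibre program (0 of 17 fallen, 2 adjusted over the list alone; -0.90, 0.00402), interferon-stimulated genes (0 of 15; -0.35, 0.00463) and inflammation genes (0 of 18, 2 adjusted over the list alone; -0.31, 0.047) stood lower. For each of these 8 lists past camera, adjusted p = 0.704 with an estimated correlation. Markers of other organs had 4 of 7 fallen, all liver genes (4 adjusted over the list alone; -4.45, 9.31e-05; adjusted p = 0.704 with an estimated correlation). Fatty acid oxidation genes (0 of 26; -0.29, 0.0321), sterol synthesis genes (2 of 26 fallen, Fdps among them, 5 adjusted over the list alone; -0.26, 0.0444) and ribosomal protein genes (0 of 52; 0.10, 0.00051) each had adjusted p = 0.859 with an estimated correlation. Complex II to V genes (0 of 39; 0.07, 0.0211) had adjusted p = 0.876 with an estimated correlation, and with the liver score as a covariate, added after the data were seen, they passed the other way with the preset correlation (-0.148, 2.53e-06).

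In all, limma called 397 genes for semaglutide against control, 121 higher and 276 lower, and after TMM rescaling 593, 288 higher and 305 lower. The count fell to 33 without control replicate 1 and 56 without control replicate 2. It was 33, 59 and 55 without semaglutide replicates 1, 2 and 3, and 112 and 127 without combination replicates 2 and 3, which enter through the shared spread. Of the 36 named calls, 8 held without any 1 library, those of Klhl38, Fkbp5, Tbc1d1, Il6ra, Eif4ebp1, Ulk1, Jun and Sgk1, and the other 28 reached adjusted p of up to 0.166. A fit without the 3 libraries richest in liver transcripts (control replicates 1 and 2 and HIIT replicate 1) leaves control replicate 3 as the only control. The spread then comes from the other groups, so only medians are given here. Those of FoxO, glucocorticoid and proteasome genes were 0.24, 0.67 and 0.31. The matrix median was -0.06, fibroblast -0.05, fatty acid oxidation -0.11, sterol synthesis -0.01, slow fibre -0.64 and interferon -0.19. Of the 276 lower genes, 132 differed between control replicates 2 and 3 by a log2 ratio within 1 of that of Alb (2.73), against 331 of all 10666 genes tested and 0 of the 121 higher ones. Of the list calls, those of angiogenesis and endothelial markers ended without semaglutide replicate 3 (camera adjusted p of 0.0653 and 0.0743). That of fatty acid oxidation ended without control replicate 1 or semaglutide replicate 3 (up to 0.622). The complex II to V call ended without control replicates 2 or 3 or semaglutide replicate 2 (up to 0.622), the sterol call without control replicate 2, HIIT replicate 1 or semaglutide replicate 1 (up to 0.335). The autophagy call ended without control replicate 3, HIIT replicate 3, semaglutide replicate 3 or any combination library (up to 0.106), and that of inflammation genes without control replicates 2 or 3, semaglutide replicates 1 or 2 or combination replicate 2 (up to 0.126).

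The combination of HIIT and semaglutide was then set against control. Cdkn1a rose by 1.54 ± 0.25 (SE, n = 3 per group, adjusted p = 0.0199) and Fkbp5 by 1.49 ± 0.20 (0.0105). Il6ra, a subunit of the interleukin-6 receptor, rose by 1.29 ± 0.18 (0.0105), Jun by 1.19 ± 0.14 (0.00813) and Fbxo32 by 1.03 ± 0.20 (0.029). Trim63 was at 0.69 ± 0.22 and did not pass (0.0868). Tbc1d1 rose by 1.41 ± 0.20, Pik3r1 by 1.32 ± 0.25 and the insulin-responsive glucose transporter Slc2a4 (GLUT4) by 0.55 ± 0.13 (adjusted p = 0.0332), from 143 to 210 FPKM. Ulk1 rose by 0.68 ± 0.10 and the autophagy receptor Sqstm1 by 0.52 ± 0.14. Among genes that fell were Alb at -6.69 ± 1.12, Kdr at -0.93 ± 0.19 and the endothelial cadherin Cdh5 at -0.55 ± 0.13. The others named were the pericyte gene Rgs5 at -0.57 ± 0.10, the slow myosin gene Myh7b at -0.96 ± 0.24 and carbonic anhydrase 3 (Car3) at -0.60 ± 0.15.

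Atrophy and FoxO targets had 6 of 22 risen (10 adjusted over the list alone; median 0.32, camera 2.6e-08; adjusted p = 0.337 with an estimated correlation). Glucocorticoid response genes had 5 risen and 1 fallen of 21 (10 and 3 adjusted over the list alone; 0.30, 1.31e-06) and autophagy genes 2 risen of 22 (3 adjusted over the list alone; 0.08, 0.000124), both with adjusted p = 0.51 with an estimated correlation. Proteasome genes had 0 of 31 risen (0.07, 1.31e-06; adjusted p = 0.589 with an estimated correlation). Branched-chain amino acid catabolism (0.10 over 22, 0.000277) and fast-muscle markers (0.28 over 10, 0.00125) stood higher with 0 members called and adjusted p = 0.51 with an estimated correlation. TCA cycle genes (0.15 over 19, 0.000124) stood higher with adjusted p = 0.796, and glycolysis genes (0.12 over 25, 0.000192) and mitochondrial biogenesis genes (0.05 over 21, 0.017) with adjusted p = 0.579, each with an estimated correlation and with 0 members called. Immediate early genes had 1 risen and 1 fallen of 24 (2 and 1 adjusted over the list alone; 0.02, 0.017) and angiogenesis genes 3 fallen of 19 (5 adjusted over the list alone; -0.29, 0.0293), both with adjusted p = 0.796 with an estimated correlation. Lower lists with adjusted p = 0.857 with an estimated correlation were ribosomal proteins (0 of 52 fallen; -0.26, 0.00457), PPAR targets (4 of 24 fallen, Cyp4a10, Cyp4a14 and Creb3l3 among them; 5 adjusted over the list alone; -0.47, 0.0462) and the slow fibre program (1 of 17 fallen, also over the list alone; -1.20, 0.0274). Markers of other organs had 4 of 7 fallen (6 adjusted over the list alone; -4.34, 0.000345; adjusted p = 0.51 with an estimated correlation).

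Of the 15 lists called higher, 3 had a median below 0, against a median of all genes of -0.13. Complex II to V genes (median 0.03, 0.000958), mitochondrially encoded genes (0.06, 0.0462) and complex I genes (median -0.01 and mean -0.02 against an upward test, 0.0404) had adjusted p = 0.857 with an estimated correlation. Regeneration genes (median -0.04, mean -0.03, upward test, 0.0405) and insulin signalling genes (median -0.01, mean 0.00289, upward test, 0.0416, 3 of 28 risen and 1 fallen, 3 and 5 adjusted over the list alone) had adjusted p = 0.51 with an estimated correlation. TMM rescaling moved the median of all genes to 0.05 and the medians of complex I, regeneration and insulin signalling genes to 0.20, 0.12 and 0.16, so their sign turned, and the latter 2 lists no longer passed (adjusted p of 0.281 and 0.154). With the liver score as a covariate 4 lists called higher passed the other way with the preset correlation, complexes II to V (-0.186, 0.000578), complex I (-0.0828, 0.00255), mitochondrially encoded genes (-0.237, 0.0029) and the TCA cycle (-0.116, 0.0143). TMM rescaling left ribosomal proteins at -0.04 with an adjusted p of 0.217, immediate early genes at 0.16 (0.24) and mitochondrially encoded genes at 0.28 (0.0637).

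limma called 668 genes, 116 higher and 552 lower, and after TMM rescaling 792, 423 higher and 369 lower. Without control replicates 1 or 2 the count was 30 or 40, and without semaglutide replicates 1, 2 or 3 it was 424, 399 or 398. Without combination replicate 1 it was 1643 but without replicate 2 or 3 it was 4 or 23. None of the 38 named calls held without every library in turn, with adjusted p up to 0.169. The fit without the 3 liver-rich libraries leaves control replicate 3 as the only control, so its count does not show which calls survive. Of the 552 lower genes, 153 shared the ratio of Alb between control replicates 2 and 3 within 1 log2 unit. List calls ended without combination replicate 3 for ribosomal proteins (0.128, also without control replicate 3), complex II to V (0.186, also control replicate 2) and mitochondrial biogenesis (0.201, also control replicate 3). The same library ended those of complex I (0.492, also control replicates 2 and 3), insulin signalling (0.118, also control replicates 1 and 2) and regeneration (0.167, also control replicate 1 and combination replicate 2). Those of immediate early genes (0.194), angiogenesis (0.0921, also control replicate 1), the slow fibre program (0.37, also control replicate 1 and combination replicate 2) and PPAR targets (0.267, also control replicate 1, combination replicate 2 and each semaglutide library) ended without combination replicate 1. The mitochondrially encoded call ended without control replicates 2 or 3, semaglutide replicates 1 or 3 or combination replicates 2 or 3 (0.291). Calls were kept with medians of 0.19 for FoxO targets and 0.13 for fast-muscle markers without control replicate 1, 0.05 for branched-chain amino acids without control replicate 2, 0.18 for glycolysis without control replicate 3 and 0.09 for the TCA cycle without combination replicate 3.

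Adding semaglutide to HIIT was tested by the combination group against HIIT alone. The ubiquitin ligase genes Fbxo32 and Trim63 rose and the collagen genes Col3a1, Col6a1, Col6a3 and Col15a1 fell, while Col1a1 (adjusted p = 0.0572), Col1a2 (0.0545) and Col5a1 (0.0567) did not pass. Fbxo32 rose by 1.23 ± 0.20 (SE, n = 3 per group, adjusted p = 0.0183) and Trim63 by 1.14 ± 0.22 (0.0284), from 150 to 338 FPKM. Ulk1 rose by 0.90 ± 0.10 (0.00398), Jup (plakoglobin) by 1.08 ± 0.13, the transcription factor Cebpd by 1.48 ± 0.31, Arrdc3 by 1.66 ± 0.33 and Ache by 0.70 ± 0.16. Nmrk2, a nicotinamide riboside kinase of muscle, fell by 2.20 ± 0.30 (0.00921). The collagen III gene Col3a1 fell by 2.18 ± 0.44, Col6a3 by 1.37 ± 0.17, Serpinh1 by 1.37 ± 0.22 and Mrtfa, a coactivator of actin-dependent transcription, by 1.55 ± 0.20. Cytoplasmic actin Actg1 fell by 1.48 ± 0.17. With the replicate number as a block in all 4 groups Col3a1 (limma adjusted p = 0.052), Cebpd (0.054) and Ache (0.0573) did not pass. With a block within HIIT and combination only they did (0.0155, 0.0131 and 0.0121). The second block was picked from these values, so it does not restore the calls.

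Extracellular matrix genes had 8 of 31 fallen and 0 risen (19 adjusted over the list alone; median -0.80, camera 1.99e-08; adjusted p = 0.59 with an estimated correlation), and fibroblast markers 4 of 15 fallen (9 adjusted over the list alone; -0.83, 0.000146; adjusted p = 0.63 with an estimated correlation). The HIIT libraries that enter here carried the higher Adipoq and Cd68 levels given above, and with the adipocyte score as a covariate the matrix and fibroblast medians were -0.68 and -0.79 and still passed camera with the preset correlation, while the genes called in this comparison fell from 321 to 38. Glucocorticoid response genes had 5 of 21 risen (10 adjusted over the list alone; 0.57, 1.82e-10; adjusted p = 0.464 with an estimated correlation) and FoxO targets 5 of 22 (9 risen and 1 fallen adjusted over the list alone; 0.50, 3.58e-10; adjusted p = 0.215 with an estimated correlation). Ribosomal proteins had 1 of 52 fallen, Rps13 at -0.51 ± 0.11 (22 adjusted over the list alone; -0.33, 1.55e-07; adjusted p = 0.746 with an estimated correlation), and their median after TMM rescaling was -0.14. Autophagy genes had 2 of 22 risen (3 adjusted over the list alone; 0.07, 0.00117; adjusted p = 0.475 with an estimated correlation) and immediate early genes 2 of 24, Jun and Btg2 (4 adjusted over the list alone; 0.15, 0.0002; adjusted p = 0.529 with an estimated correlation). The 17 lists past camera with the preset correlation also held proteasome, glycolysis, branched-chain amino acid, regeneration, fast-muscle, mitochondrial biogenesis, TCA cycle, neuromuscular, calcium handling and insulin signalling genes, with medians of 0.03 to 0.29. After TMM rescaling insulin signalling no longer passed (0.0635). With an estimated correlation 0 of the 17 passed.

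limma called 321 genes, 112 higher and 209 lower, at a median of all genes of -0.12; after TMM rescaling the median was 0.03 and 770 genes were called, 552 higher and 218 lower. With the block within these 2 groups, added after the correlations of same-number libraries were seen, 1370 were called, 305 higher and 1065 lower, with the 321 among them. Without a block the count was 69 or 67 without HIIT replicates 1 or 3, 205 without control replicate 1, and 206 or 196 without semaglutide replicates 2 or 3. It was 1574 without combination replicate 1 and 18 or 40 without combination replicates 2 or 3. Without the 3 liver-rich libraries it was 42, of which 38 were among the 321. Of 36 named calls 6 held without any 1 library, those of Jup, Mrtfa, Sec14l5, Actg1, Col6a3 and Ulk1, and the others reached adjusted p of up to 0.164. The mitochondrial biogenesis (0.106) and TCA cycle (0.505) calls ended without HIIT replicate 1 or combination replicate 3, calcium handling (0.139) without HIIT replicate 3 or combination replicates 2 or 3, the neuromuscular call (0.0536) without combination replicate 1, and branched-chain amino acids (0.0501) without combination replicate 3. The immediate early median was -0.05 and 0.26 without combination replicates 1 and 3, that of regeneration 0.31 and 0.12 without the same, that of glycolysis 0.23 and 0.03 without HIIT replicates 2 and 3 and that of fast-muscle markers 0.15 without HIIT replicate 3, with these calls kept.

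Adding HIIT to semaglutide was tested by the combination group against semaglutide alone. limma called 1 feature, MSTRG.18204.16, an assembled feature without a gene name that fell by 1.20 ± 0.14 (adjusted p = 0.0267). It was named after its values were seen. In all, 1292 genes lay at an unadjusted p under 0.05. The rule's genes did not pass. Dusp29, a muscle phosphatase gene, was at 0.98 ± 0.16, the lysine methyltransferase gene Mettl21e at 0.89 ± 0.19, the valine catabolic enzyme Hibadh at 0.33 ± 0.07, Ppfibp2 at -0.98 ± 0.17 and Clec2d at -0.66 ± 0.12, all with an adjusted p of 0.28. All 52 ribosomal protein genes lay below 0, with a median of -0.34, and 33 fell when adjusted over the list alone against 0 over all genes (camera 8.95e-16; adjusted p = 0.746 with an estimated correlation; median -0.22 after TMM rescaling). Rps13 was at -0.50 ± 0.11. All 19 TCA cycle genes lay above 0 (median 0.11, 5.98e-06; adjusted p = 0.746 with an estimated correlation), and branched-chain amino acid genes had a median of 0.11 over 22 (2 risen adjusted over the list alone, Hibadh and Bcat2 leading; 2.9e-07; adjusted p = 0.602 with an estimated correlation). In all, 19 lists passed camera with the preset correlation (11 after TMM rescaling) and 0 with an estimated one. Only these 3 calls held without any 1 library, with TCA cycle medians of 0.17 and 0.04 without combination replicates 1 and 3 and a branched-chain median of 0.06 without the latter.

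Combination replicate 1 stood apart within this group. Without it limma called 557 genes, 41 higher and 516 lower, and after TMM rescaling 358, 124 higher and 234 lower, with the median of all genes moving from -0.11 to 0.03. Without 8 of the other libraries in turn the count was 0. White adipocyte (median 0.40, adjusted p = 0.0143), macrophage (0.31, 0.0132), extracellular matrix (0.08, 0.0012) and fibroblast (0.11, 0.009) lists were higher with adjusted p = 0.772, 0.848, 0.785 and 0.772 with an estimated correlation. Each of these calls ended without combination replicate 1, at adjusted p of up to 0.378, 0.339, 0.109 and 0.0945, the adipocyte call also without semaglutide replicate 2. That library had an Adipoq of 52.8 FPKM against 15.8 and 10.7 in replicates 2 and 3. Calls for fatty acid oxidation (median 0.03, up to 0.704), mitochondrial biogenesis (0.08, 0.143) and ketone use (0.08, 0.143) ended without semaglutide replicate 3 or combination replicate 3, and that of glycolysis (0.05, 0.0649) without the former. Those of calcium handling (0.10, 0.0617), chaperones (0.03, 0.345) and the fast fibre program (0.08, 0.0717) ended without combination replicate 2, the first 2 also without replicate 3 and chaperones also without semaglutide replicate 2. Calls for autophagy (0.05, 0.216), myokines (0.09, 0.102), interferon-stimulated genes (0.11, 0.14), inflammation (0.04, 0.124) and fast-muscle markers (0.18, 0.132) ended without combination replicate 1 and at least 1 other library. Without replicates 2 and 3 the ribosomal median was -0.12 and that of the TCA cycle genes -0.01.

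The series title speaks of synergy, which on the log2 scale is tested by the interaction of HIIT and semaglutide. limma called 0 genes, with 822 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0806. Among the rule's genes Clec2d was at -0.98 ± 0.17 (adjusted p = 0.534), H2az1 at -0.64 ± 0.12, the muscle sodium channel gene Scn4a at 0.56 ± 0.12 and Dusp8 at 0.63 ± 0.14, the last 3 at 0.632. Without combination replicate 1 the count was 24, 2 higher and 22 lower. Of 45 lists 13 passed camera with the preset correlation, led by ribosomal proteins, all 52 of which were below 0 (median -0.44, 6.45e-19), and each had adjusted p = 0.901 with an estimated correlation.

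Averaged over exercise, semaglutide changed 1796 genes (6 libraries against 6), 500 higher and 1296 lower, and 2143 after TMM rescaling, 1282 higher and 861 lower, with the median of all genes moving from -0.08 to 0.03. Fbxo32 rose by 1.30 ± 0.14 (adjusted p = 0.000833), Arrdc3, an arrestin-domain gene, by 1.65 ± 0.23, Pik3r1 by 1.33 ± 0.18 and Prima1, the membrane anchor of acetylcholinesterase, by 1.35 ± 0.19. Alb fell by 4.93 ± 0.79, Ttr by 3.45 ± 0.66 and the urinary protein gene Mup3 by 3.04 ± 0.51. FoxO targets had 11 risen and 1 fallen of 22 (12 and 1 adjusted over the list alone; median 0.44, 9.91e-11; adjusted p = 0.172 with an estimated correlation), and matrix genes 18 fallen of 31 (24 adjusted over the list alone; -0.65, 4.4e-08; adjusted p = 0.633 with an estimated correlation). All 12 macrophage markers were below 0 as well (median -0.70, camera 0.0842; adjusted p = 0.881 with an estimated correlation), white adipocyte markers had a median of -0.62 (0.194; adjusted p = 0.881 with an estimated correlation), and Cd74 was at -1.20 ± 0.37 (0.0505) and Fabp4 at -1.17 ± 0.43 (0.0894). Whether a change in the share of these cells underlies the matrix fall was not tested for the averaged effect. Without the 3 liver-rich libraries the matrix median was -0.06 for semaglutide against control and -0.615 for the combination against HIIT. All 10 named calls held without any 1 library (adjusted p up to 0.0313), which does not test for liver RNA, since several libraries carry liver transcripts. Alb and Ttr are among the liver genes weighed below. With the liver score as a covariate Ttr turned sign to 0.1549. Far fewer genes were called with that score or with the adipocyte score, as given below. The count was 874 or 1076 without combination replicates 2 or 3 and 1110 or 1048 without control replicates 1 or 2. It was 987 or 1023 without semaglutide replicates 1 or 2 and 1153 without HIIT replicate 1.

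Exercise averaged over semaglutide gave 0 calls by limma, with 1341 genes at an unadjusted p under 0.05. Mettl21e was at 0.77 ± 0.14 and Ppfibp2 at -0.73 ± 0.12, both at an adjusted p of 0.252, and the EGF receptor inhibitor Errfi1 at -0.71 ± 0.15 (0.292). Without combination replicate 1 the count was 251 and without HIIT replicate 1 it was 1. Semaglutide against HIIT, the direct comparison of the single interventions, gave 490 calls, 251 higher and 239 lower (781 after TMM rescaling, 485 higher and 296 lower). Arrdc3 was higher by 2.17 ± 0.33 and the matricellular gene Ccn1 by 1.76 ± 0.26, and Col3a1 lower at -2.85 ± 0.44, Col1a1 at -2.12 ± 0.35 and the clock output gene Dbp at -2.37 ± 0.28 (adjusted p = 0.0035). Markers of other cells were below 0 without passing, Cd68 at -2.10 ± 0.68 (adjusted p = 0.102), Adipoq at -1.91 ± 0.73 (0.153) and Cd74 at -1.77 ± 0.53 (0.0816). White adipocyte markers had a median of -1.40 (1 of 14 fallen, 8 adjusted over the list alone; camera 0.00243; adjusted p = 0.703 with an estimated correlation) and macrophage markers of -1.09 (0 of 12; 0.00116; adjusted p = 0.88 with an estimated correlation). The count was 234 or 173 without HIIT replicates 1 or 3 and 66, 148 or 183 without semaglutide replicates 1, 2 or 3, and 6 of 10 named calls held without any 1 library. The F test over the 4 groups called 652 genes, from 115 without semaglutide replicate 1 to 1674 without combination replicate 1.

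Both drug comparisons share their 3 control libraries. Of their calls 57 were higher and 227 lower in both and 0 opposite, where independent lists would share 1.32 and 14.3 and unchanged simulated groups shared 0. Across genes, which are not independent replicates, the fold changes correlated at r = 0.88 (0.502 in 100 simulated sets with no effect). Their signs agreed for 74.2% of genes (66.7% simulated). Their covariance was 0.18 against 0.0232 simulated, a difference of 0.157. For HIIT and semaglutide r was 0.57 (0.503 simulated) and the covariance 0.0827 (0.0233 simulated), a difference of 0.0594, and for HIIT and the combination r was 0.649 (0.501) and the covariance 0.0926 (0.0231), a difference of 0.0694. The signs agreed for 55.4 and 57.8% of genes in these 2 pairs, below the 66.7% simulated. With 3 controls the libraries cannot be split into parts of at least 2, and part of the excess may come from the shared controls. The simulated genes varied independently of each other, which real genes do not. The simulated values can therefore be too low, and the differences from them do not measure a shared effect.

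**Figure D4:**
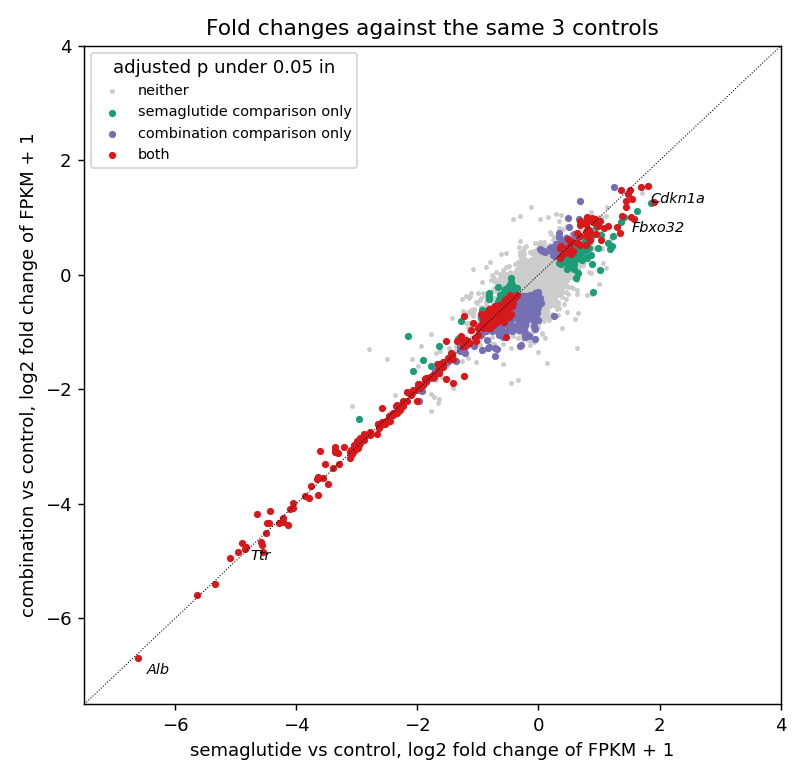
Each point is 1 of 10666 genes, with the log2 fold change of FPKM + 1 of semaglutide against control on the x axis and of the combination against control on the y axis; colours mark an adjusted p under 0.05 in either or both comparisons and the dotted line equality. Liver genes such as Alb lie at the lower left (-6.61 and -6.69) and Fbxo32 at the upper right (1.38 and 1.03).

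**Figure D5:**
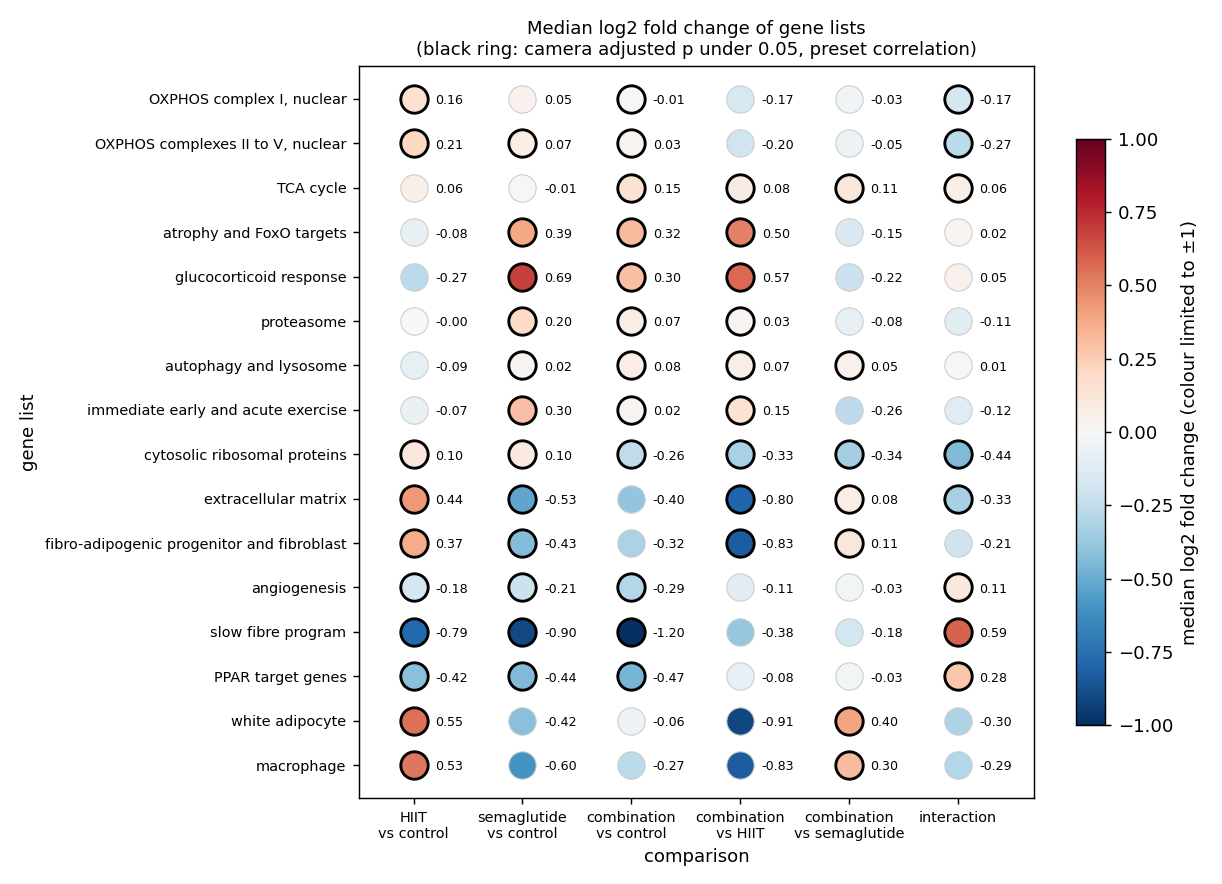
Median log2 fold change of 16 gene lists (y axis) in 5 comparisons and the interaction (x axis), as colour and as printed values, with a black ring where camera with the preset correlation gave an adjusted p under 0.05. FoxO targets are at 0.39, 0.32 and 0.50 in the comparisons of injected with other mice, and matrix genes at 0.44 under HIIT and -0.53 under semaglutide; 0 lists pass with an estimated correlation.

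Of the fixed genes of metabolism and fibre type, 3 were called in any of these comparisons, Fbxo32, Trim63 and Slc2a4. Pdk4, a switch from glucose to fat oxidation, was at -0.89 ± 0.64 under HIIT, 0.49 ± 0.64 under semaglutide and -0.34 ± 0.64 in the combination group (adjusted p of 0.728, 0.726 and 0.773 by limma). Myh4 was at -0.13 ± 0.17, 0.09 ± 0.17 and 0.25 ± 0.17, and Mstn (myostatin) at 0.18 ± 0.24, 0.45 ± 0.24 and 0.46 ± 0.24, none past the threshold. The hexokinase gene Hk2, Cpt1b, Ucp3, Vegfa, Irs1, Irs2, Cd36 and Scd1 did not pass either. Lepr, the gene mutated in db/db mice, had FPKM of 0.079 to 0.18. Glp1r, the receptor of semaglutide, was listed at 0 in 11 of 12 libraries with a highest value of 0.0041, Il6 in 7 and Fgf21 in 5.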

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

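The tests of liver RNA, of muscle expression, of the hour of collection, of food intake and of depth were chosen after the result was seen, and those of scaling, transcript length and other splits before. What was flagged is a difference between groups. For 13 lists the effect of HIIT in injected mice differed from its effect in mice without injections by camera on the interaction, with the preset correlation. Their medians were -0.443 for ribosomal proteins, 0.152 for branched-chain amino acid catabolism, 0.279 for PPAR targets, -0.269 for complexes II to V, -0.174 for complex I and 2.71 for markers of other organs. They were 0.22 for fatty acid oxidation, 0.214 for calcium handling, 0.591 for the slow fibre program, 0.0986 for mitochondrial biogenesis, 0.0591 for the TCA cycle, -0.331 for the extracellular matrix and 0.106 for angiogenesis. With an estimated correlation each had an adjusted p of 0.901, and no single gene passed. The calls for ribosomal proteins, branched-chain amino acids and other organs held without any 1 library, with medians of 0.0864 and 0.0868 for branched-chain amino acids without control replicate 1 and combination replicate 3 and of 1.78 for other organs without HIIT replicate 3. Those of the other 10 lists each ended without at least 1 library, at adjusted p of up to 0.852 (TCA cycle).

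The first pattern weighed is the fall of liver transcripts from controls to injected mice. Over 18 liver genes the log2 ratio between 2 libraries of a group had an SD of 0.277 (control 2 to 3), 0.31 (control 1 to 3) and 0.252 (HIIT 1 to 2) around medians of 2.79, 1.83 and 2.85, against 0.59, 0.47 and 0.62 over all genes. That the genes move by nearly 1 ratio fits liver RNA in the libraries (largest SD 0.31), which could have entered at dissection or later, and does not show when. Lower expression in muscle under semaglutide cannot be told apart by group means, since HIIT mice, which got no drug, were also lower than controls. Their mean log2 level over the 18 genes was lower by 3.5 (value -3.5, SE 1.98), beside -7.19 and -7.25 for semaglutide and the combination. These levels used a smaller pseudocount than log2(FPKM + 1). Their sizes therefore depend on values near 0 and do not compare with the fold changes above. The labels name liver among the harvested tissues.

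The second pattern is the higher level of FoxO, glucocorticoid and proteasome genes in injected mice, a median of 0.162 over 67 members, 23 of which rose and 2 fell (0.303, 40 and 1 after TMM rescaling). If liver RNA in the controls were the cause, the median should fall without the 3 liver-rich libraries, but it was 0.209. It was 0.135 to 0.205 without any 1 library. Among mice without injections the fit without the 3 libraries leaves control replicate 3 as the only control, itself with Alb at 107.8 FPKM. It also leaves HIIT replicates 2 and 3, with Alb at 27.61 and 3.799. Liver transcripts thus remain on that side, so this fit cannot exclude liver RNA. Another hour of collection cannot be told apart. The 4 clock genes that run opposite to Dbp had a median of -0.197, with Cry1 lower and Nfil3 higher. The median of the SEs of these single genes was 0.1, which is not an error of their median. A response like that to lower food intake, which semaglutide could bring, cannot be told apart either. Its test, 11 PPAR targets expressed in muscle, had a median of 0.0295 with an SD of 0.49. Members lay on both sides, such as Pdk4 at 0.522 and Angptl4 at -1.26. The injecting itself cannot be told apart from the drug, since the treatment labels name no injection for the other mice.

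The third pattern is that combination replicates 2 and 3 stand apart from replicate 1. Lower depth is argued against as a cause shared by both. Replicate 2 was estimated at 21.2 M fragments, where the other 10 libraries lie at 17.2 to 21.3 with a median of 19. Replicate 3 was at 18.1, below that median and below replicate 1 (18.4). Scaling is argued against as the whole cause, since 275 of the 557 genes called without replicate 1 were still called in the same direction after TMM rescaling, which called 358 in all. Transcript length was tested for the ribosomal genes, whose median of -0.336 lay at percentile 0 of 10000 lists matched on length and level (-0.188 to 0.0645). The lengths were those of the longest annotated transcript, with medians of 1124 bases for ribosomal and 1141 for matched genes. These can exceed the transcripts that were sequenced, so the match does not settle length as a cause. No biological explanation was tested, because the design names no difference between these animals.

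Other splits of the 12 libraries bear on whether chance could give the counts. Among 100 splits, the real one was the only 1 to reach its count for the F test (652, highest other 605). The same held for semaglutide averaged over exercise (1796, highest other 187). A share of 1 in 100 argues against chance for these counts but does not exclude it, and for the F test another split came close. For exercise averaged over semaglutide and for the interaction the real count was 0, which all 100 splits reach by construction, so the number that reach it says nothing. The highest other counts there were 450 and 267. With 10 splits of 6 libraries there are too few for a share under 0.05. There the real and highest other counts were 0 and 216 for HIIT against control (which all 10 reach by construction), 397 and 0 for semaglutide against control, 668 and 0 for the combination against control, 321 and 104 for the combination against HIIT, 1 and 0 for the combination against semaglutide, and 490 and 0 for semaglutide against HIIT, with only the real 1 reaching its count in the last 5. The 216 genes came from control replicates 1 and 2 with HIIT replicate 1 against the other 3, which are the liver-rich libraries, and the 104 from HIIT replicates 1 and 2 with combination replicate 1. The split with 216 genes points to structure among the samples other than their groups. The split with 104 genes does not show this, because it lies partly along injection, with 1 injected library against 2. Nor do the splits that called 450 and 267 genes, with 5 injected libraries against 1 and 4 against 2. Of their genes 283 and 160 are among the 1796.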

How the results depend on the processing

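The fits without the 3 liver-rich libraries, with the liver or adipocyte score, without combination replicates 2 and 3, and with a block within HIIT and combination only were chosen after the data were seen, and all others before. Counts below are of genes with an adjusted p of 0.05 unless lists are named, and the cause of a change was not tested except where fewer genes or libraries entered.

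Across the settings chosen beforehand, named genes that had passed gave 2453 values, of which 1835 kept direction and threshold and 618 kept direction only. Named genes that had not passed gave 12311 values, 12065 on the same side and 246 now past it. Lists that had passed gave 1600 values, 1337 kept and 263 weaker. In the settings added later named genes that had passed kept 234 of 556 values, 300 were weaker and 22 turned sign, and lists kept 283 of 417, with 129 weaker and 5 turned.

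Without a filter the F test gave 296, the combination against HIIT 195 and the combination against semaglutide 0. With the filter at FPKM 5 the F test gave 377, semaglutide against control 208, the combination against control 242 and against semaglutide 0, and semaglutide averaged over exercise 970. The genes shared by both drug comparisons were then 120. A pseudocount of 0.1 gave 0 for the combination against semaglutide. TMM rescaling gave 1035 for the F test, 770 for the combination against HIIT, 781 for semaglutide against HIIT, and 11 lists for the combination against semaglutide. Array weights gave 2952 for the F test, 803 for semaglutide and 2714 for the combination against control, 1717 for the combination against HIIT and 1267 against semaglutide, 1 for the interaction, 1 for exercise and 2835 for semaglutide averaged, and 609 shared. Fits to 6 libraries gave 168 for semaglutide and 122 for the combination against control, 9 for the combination against HIIT and 0 against semaglutide. Camera with an estimated correlation called 0 lists in each of the 6 comparisons.

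With the replicate number as a block (replicate block) the combination against semaglutide gave 0, and no other count moved by more than 1.5 times. For the combination against HIIT it gave 335, of which 247 were among those called without it. Besides the 3 genes given in the report, Pik3r1 (adjusted p = 0.0582) and Sqstm1 (0.0595) then did not pass and Car3 (0.0387) did. With the block within HIIT and combination only (1370 genes) all 36 named calls and 17 lists were kept, and 19 further named genes and 1 further list passed.

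Without the 3 libraries with the most liver transcripts the F test gave 150, semaglutide against control 145, the combination against control 162, against HIIT 42 and against semaglutide 0, semaglutide against HIIT 88, semaglutide averaged 349, the shared genes 127, and HIIT against control 21 lists. The fit without the 3 liver-rich libraries leaves control replicate 3 as the only control. Its counts for comparisons with control, and of shared genes, therefore do not show which calls survive. With the adipocyte score the F test gave 253, the combination against HIIT 38 and against semaglutide 0, semaglutide against HIIT 236 and semaglutide averaged 586. Without combination replicates 2 and 3 the F test gave 115, semaglutide against control 109, the combination 0 against control, 0 against HIIT and 0 against semaglutide, semaglutide averaged 266 and the shared genes 0, with 12 lists for the combination against control and 10 against semaglutide.

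With the liver score as a covariate the F test gave 24, HIIT against control 1, semaglutide against control 1, the combination 1 against control and 28 against HIIT, semaglutide against HIIT 70, exercise averaged 1, semaglutide averaged 2, the shared genes 1, and the combination against HIIT 11 lists. The score is 0.253 to 0.8861 in injected mice, 0.838 to 5.112 under HIIT and 4.25 to 6.912 in controls, and is built from Alb, Apoa1, Ttr and Serpina1a, which by construction takes up what these genes differ by. Of the values that turned sign the lists passed camera with the preset correlation the other way and the genes did not pass. For semaglutide against control they were complexes II to V at -0.148 and the genes Apoa2 0.60, Ttr 0.1582, Gc 0.339, Apoc1 0.4411, Hpx 0.1631, Cyp4a10 0.07939, Cyp4a14 0.387, Creb3l3 0.1449, Serpina1a 0.05429 and Apoa1 0.3366. For the combination against control they were complex I at -0.0828, complexes II to V -0.186, mitochondrially encoded genes -0.237, the TCA cycle -0.116, Apoa2 0.4331, Apoc3 0.5515, Gc 0.3119, Fabp1 0.7719, Ttr 0.2728, Cyp4a10 0.08551, Cyp4a14 0.2817, Creb3l3 0.1366, Serpina1a 0.1168 and Apoa1 0.3534. For semaglutide averaged over exercise they were Ttr 0.1549 and Saa2 0.01518.

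Leaving out each library in turn gave 115 to 1674 for the F test, 0 to 1 for HIIT, 33 to 552 for semaglutide and 4 to 1643 for the combination against control. It gave 18 to 1574 for the combination against HIIT, 0 to 557 against semaglutide, 66 to 689 for semaglutide against HIIT, 0 to 24 for the interaction, 0 to 251 for exercise and 874 to 2547 for semaglutide averaged. Lists past camera numbered 9 to 19, 14 to 21 and 13 to 25 for HIIT, semaglutide and the combination against control. They numbered 15 to 21 and 10 to 20 for the combination against HIIT and semaglutide, and 7 to 15 for the interaction. At 17.2 to 21.3 M fragments the depth limits genes under an FPKM of 1, where a 1 kb transcript has fewer than about 21 fragments.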

Other observations

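Clock genes and fibre type add to the comparisons above. The clock list did not pass camera for semaglutide against control (median -0.20 over 18 genes, adjusted p of 0.079), but single members did, with 1 risen and 3 fallen (2 and 6 adjusted over the list alone). Dbp, a transcription factor that follows the clock, fell by 2.15 ± 0.28 (adjusted p = 0.00823). Averaged over exercise it was at -1.72 ± 0.20, the clock repressor Nr1d1 at -1 ± 0.12 (both 0.00119) and Ciart at -1.07 ± 0.22 (0.0123). The hour of collection is not given in the sources used here.

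The myosin profile is that of fast muscle, with Myh4 at 82.3 to 95% of the 4 adult myosins, while the protocol names soleus, a muscle with many slow fibres in mice. Myh7 was at 0.0559 to 1.52%, and these shares argue against soleus as the main tissue of any library. Which fast muscle was sampled cannot be settled from these values.

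Of the 45 lists, 10 passed camera with the preset correlation in none of the 6 comparisons, the interaction or the averaged effects. They are ER stress, antioxidant, circadian clock and cell cycle genes, and markers of Schwann cells, brown adipocytes, erythrocytes, satellite cells, smooth muscle and tenocytes.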
